A study of Mus musculus with 8 samples.

How the data were processed

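Kupffer cells were sorted from livers of wild-type C57BL/6J mice 2 h after CLP or sham surgery, with 4 libraries per group. RNA was isolated with the Aurum Total RNA kit, and libraries were made with the Illumina TruSeq stranded kit and sequenced on an Element AVITI with Cloudbreak chemistry, per the labels' protocols. The antibodies and the gate of the sort are not given in the sources used here.

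The deposited count table holds 55414 Ensembl genes for 8 libraries, and its values are whole read counts. FastQC, STAR 2.7.10b, featureCounts, DESeq2 and the mouse assembly mm39 were used upstream, per the submitters' processing notes. Their settings, the annotation release and the strand setting of the count are not given in the sources used here. Reads were not aligned again.

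Gene names, biotypes and transcript GC content and length were taken from GENCODE M21, which is on the earlier assembly GRCm38, so no coordinates are printed. Symbols are the older ones of that release. A symbol was found for 52081 IDs, which hold 99.8% of the counts, and 800 of 806 list entries were in the table.

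Counts were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 by a robust quasi-likelihood F-test with surgery as the only term, in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over 14655 genes with a threshold of 0.05. CPM values are TMM-scaled, with sample SDs, and the SE of a log2 fold change is its absolute value over the square root of F, an approximation. Gene lists with at least 5 members tested were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, each adjusted over 31 lists. Summed marker CPM and library measures were compared by two-sided exact permutation over 35 splits, where the smallest p is 0.0286. Principal components used log2 CPM with a prior count of 2.

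The groups, the comparison, the 32 lists, the named genes, the alternatives and the thresholds were set before the data were examined. Named genes were drawn from the 13 genes fixed in advance, the 5 largest rises and falls past the threshold with a mean of at least 10 CPM in the higher group, no overlap between the groups and a symbol that is not a clone name, the 3 members with the smallest p in each function list, and the 2 most abundant members of each cell type list. Total-count scaling and the GC correction were added after the data were seen. Alternatives were run with DESeq2 1.42.0 and limma voom, and GC content was read with Biostrings 2.70.1.

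In a self-test, 50 genes each were simulated at 4 sizes of fold change, 1.5, 2, 4 and 8, among 14655 genes. edgeR recovered 13, 30, 48 and 50 of them, with 8 false calls among 149. DESeq2 made 32 false calls among 185 and voom 10 among 151. camera and fry called the planted list and 0 of 50 null lists. The simulated genes varied independently of each other, and few were changed. The self-test therefore does not show how the list tests behave when genes are correlated. Nor does it show how the fits behave under a large shift in composition.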

Results

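RNA was sequenced from Kupffer cells, the resident macrophages of the liver, which were isolated by fluorescence-activated cell sorting from wild-type C57BL/6J mice. The livers were taken 2 h after caecal ligation and puncture (CLP), an operation that releases gut bacteria into the abdomen and is used as a model of sepsis, or after a sham operation (Sham). There were 4 libraries per group, and each held about 23311900 to 28724900 counts over genes, with no difference found between the groups (exact permutation test, two-sided, p = 0.743). The labels do not say outright that each library came from a separate mouse, so p-values measure the spread between these samples. The study was set up to look for the mechanism of hemolysis, the rupture of red blood cells, in sepsis. The single comparison asks how the early response to CLP changed transcript levels in the cells that clear damaged red cells and hemoglobin.

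Within 2 h of CLP, sorted Kupffer cells held far more transcripts of cytokines, chemokines, NF-kB feedback genes and coagulation genes than cells sorted after sham surgery. Tested markers of neutrophils, platelets and B cells also rose, in 16 of 16, 13 of 14 and 12 of 15 cases. Of these, 9, 6 and 11 were under 1 CPM in Sham. Markers near 0 there could pass the count filter only by being high in CLP. The summed B cell markers did not rise, at 281 CPM in CLP and 287 CPM in Sham. The part of the changes that came from other cells in the sorts was not measured. Heme oxygenase 1, ferritin and the heme-responsive regulators Spic and Bach1 rose, while the iron exporter ferroportin (Slc40a1) fell. The most abundant Kupffer cell marker, Clec4f, differed by a log2 fold change of only 0.27. Of 14655 genes tested with edgeR's quasi-likelihood test, 7963 passed an adjusted p of 0.05, of which 3644 were higher and 4319 lower in CLP. Changes of at least 2-fold numbered 1872 upward and 2327 downward, and changes of at least 8-fold numbered 314 and 163. In 7247 genes (49.5%) the 4 CLP and 4 Sham libraries did not overlap, against 2.86% by chance. Genes at least 4-fold higher took 15.9% of the counts in CLP and 2.97% in Sham.

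The groups were separated on the first principal component, which held 76.7% of the variance. CLP replicate 1 stood apart from the other 3 CLP libraries on the second component (10.0% of the variance). Its log2 CPM values correlated with theirs across genes at r = 0.968 to 0.972, against 0.986 to 0.987 among those 3. Without it, 9232 genes passed the threshold, 4235 higher and 4997 lower. All changes are given relative to the scaling by trimmed mean of M-values (TMM), whose factors were 0.825 ± 0.0165 in CLP and 1.21 ± 0.0557 in Sham. Scaling by total counts alone, a setting chosen after the factors were seen, gave a median shift of the log2 fold changes of -0.55. It gave 1715 genes higher and 8292 lower, so that 17.1% of calls were upward in place of 45.8%. A correction for GC content, also chosen after the data were seen, gave 4597 higher and 3588 lower (56.2% upward). The direction of small changes therefore depends on the scaling.

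**Figure D1:**
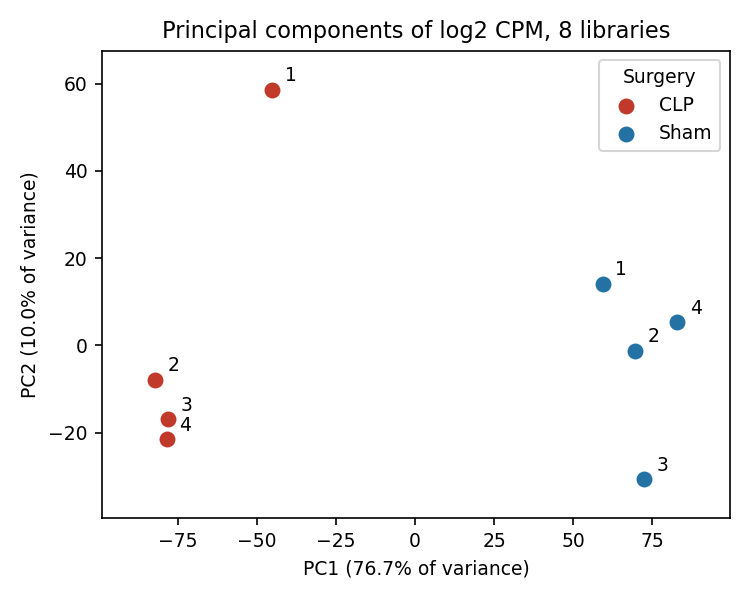
First and second principal components of log2 CPM for the 4 CLP and 4 Sham libraries, with replicate numbers beside the points and the percent of variance on each axis. The first component (76.7%) separates the surgeries, and CLP replicate 1 lies apart from the other CLP libraries on the second (10.0%).

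The largest rise was that of Cxcl3 (ENSMUSG00000029379), a chemokine that attracts neutrophils, at 636 ± 267 CPM in CLP and 0.211 ± 0.208 CPM in Sham (SD, n = 4). Its log2 fold change was 11.53 ± 0.62 (SE; edgeR adjusted p = 1.1e-06), and the pooled counts of 53113 and 27 gave a ratio of 2948, with an exact 95% counting interval of 2026 to 4475. Such intervals cover counting error only. Sham replicate 1 held 16 of the Sham counts of Cxcl3, and without it the ratio was 5388. Next came Sphk1 (ENSMUSG00000061878), a sphingosine kinase, with a log2 fold change of 10.62 ± 0.54, and Slamf1 (ENSMUSG00000015316), a surface receptor of lymphoid and myeloid cells, with 9.88 ± 0.72. Slamf1 reached 46.7 CPM in CLP replicate 1 and 264 to 282 CPM in the other 3 CLP libraries. Tnfrsf9 (ENSMUSG00000028965), the costimulatory receptor CD137, had 1800 counts in CLP and 3 in Sham, a ratio of 899 with an interval of 307 to 4365. All 3 Sham counts of Tnfrsf9 came from Sham replicate 1, so without that library the ratio has no upper bound. Csf3 (ENSMUSG00000038067), the granulocyte colony-stimulating factor, was at 355 ± 121 CPM in CLP and 0.464 ± 0.326 CPM in Sham. The largest fall was in Ddit4 (ENSMUSG00000020108), a stress-responsive inhibitor of mTORC1 signalling, from 304 ± 86.8 CPM in Sham to 7.68 ± 1.94 CPM in CLP (log2 fold change -5.31 ± 0.29, edgeR adjusted p = 1.1e-06). Ajuba (ENSMUSG00000022178), a LIM-domain scaffold protein, had a log2 fold change of -4.98 ± 0.23. Values were -4.80 ± 0.26 for the homeobox factor Hhex (ENSMUSG00000024986), -3.99 ± 0.29 for the vesicle GTPase Rab3a (ENSMUSG00000031840) and -3.90 ± 0.44 for the G protein subunit Gna15 (ENSMUSG00000034792). Gna15 was at 18.9 CPM in Sham replicate 3 and 9.62 to 10.3 CPM in the other Sham libraries.

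Of the genes tested, 24.9% rose and 29.5% fell, which is the background against which members of each list fixed before the data were examined can be read. Counts are given over all genes tested, and counts adjusted over the list alone were the same unless stated. Members named because a count was 5 or fewer were chosen after their values were seen. All 22 inflammatory cytokine and mediator genes tested rose, with a median log2 fold change of 4.00 (camera adjusted p = 1.0e-10, or adjusted p = 0.221 with an estimated correlation). The list held 28 genes, and 4 of those tested were under 1 CPM in Sham. So were 5 of the chemokine and 4 of the coagulation genes tested below. Genes near 0 in Sham could pass the count filter only by being high in CLP. Tnf rose from 13.5 ± 6.84 to 359 ± 119.8 CPM and Il1b from 283 ± 136 to 3026 ± 1672 CPM. Il6 reached 597 ± 360.2 CPM from 18.1 ± 5.70 CPM, and Il10, an anti-inflammatory cytokine, 932 ± 430.2 CPM from 21.7 ± 3.68 CPM. Their log2 fold changes were 4.73 ± 0.43, 3.42 ± 0.46, 5.05 ± 0.55 and 5.42 ± 0.41 in that order, and edgeR adjusted p-values lay between 5.1e-06 and 1.3e-04. Tnfsf9, the ligand of CD137, rose by 7.37 ± 0.43 and the cytokine subunit Il27 by 4.69 ± 0.29 on the log2 scale.

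Of 25 chemokine genes tested, 20 rose and 2, Ccl17 and Cx3cl1, fell (median log2 fold change 2.83; camera adjusted p = 9.5e-08, or adjusted p = 0.221 with an estimated correlation). Besides Cxcl3, the neutrophil attractant Cxcl2 stood at 1773 ± 617 CPM in CLP and 33.5 ± 7.76 CPM in Sham, and Ccl4, which attracts monocytes and T cells, at 1329 ± 559 CPM in CLP and 10.5 ± 4.56 CPM in Sham. All 30 NF-kB feedback and primary target genes rose (median 2.60; camera adjusted p = 1.7e-15, or adjusted p = 0.3 with an estimated correlation). Examples were Nfkbia, the inhibitor of NF-kB, at 1681 ± 91.4 CPM in CLP and 377 ± 66.0 CPM in Sham, the Schlafen family gene Slfn2 with a log2 fold change of 2.69 ± 0.14 and the apoptosis regulator Cflar with 2.92 ± 0.20. That list also holds the near-identical genes Bcl2a1a, Bcl2a1b and Bcl2a1d, between which the counting may have split reads.

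Genes of heme and iron handling mostly rose: 20 of 32 tested were higher (21 adjusted over the list alone) and 3, Slc40a1, Ncoa4 and Aco1, were lower. The list shares 9 of its 33 entries with other lists. Among these are Lcn2 of the neutrophil list and Hpx of the hepatocyte list, which both rose. The median log2 fold change was 0.68 (camera adjusted p = 1.5e-04, or adjusted p = 0.3 with an estimated correlation). Hmox1 (ENSMUSG00000005413), which breaks heme down, was at 6375 ± 1114 CPM in CLP and 1860.4 ± 364 CPM in Sham (log2 fold change 1.78 ± 0.18, edgeR adjusted p = 2.4e-05). Bach1, a repressor of Hmox1 that heme inactivates, rose from 187 ± 38.9 to 1988 ± 372 CPM (3.41 ± 0.20), and Fth1, the ferritin heavy chain, from 1119 ± 192 to 4642 ± 489.5 CPM (2.05 ± 0.15). Spic, a transcription factor of macrophages that recycle red cell iron, rose by 2.45 ± 0.34 on the log2 scale, with 958 CPM in CLP replicate 1 and 1449 to 1519.9 CPM in the other CLP libraries. Slc48a1, which carries heme out of the phagolysosome, rose less (0.77 ± 0.14) and was not past the threshold with total-count scaling (log2 fold change 0.22, edgeR adjusted p = 0.127). Slc40a1 (ENSMUSG00000025993) fell from 4345 ± 353 to 2450.5 ± 451 CPM (-0.83 ± 0.15, edgeR adjusted p = 9.4e-04). Cd163, the receptor for hemoglobin bound to haptoglobin, was at 3178 ± 239.6 CPM in CLP and 3379 ± 291 CPM in Sham and did not pass (log2 fold change -0.09 ± 0.12, edgeR adjusted p = 0.557). With total-count scaling Cd163 was lower, with a log2 fold change of -0.64.

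**Figure D2:**
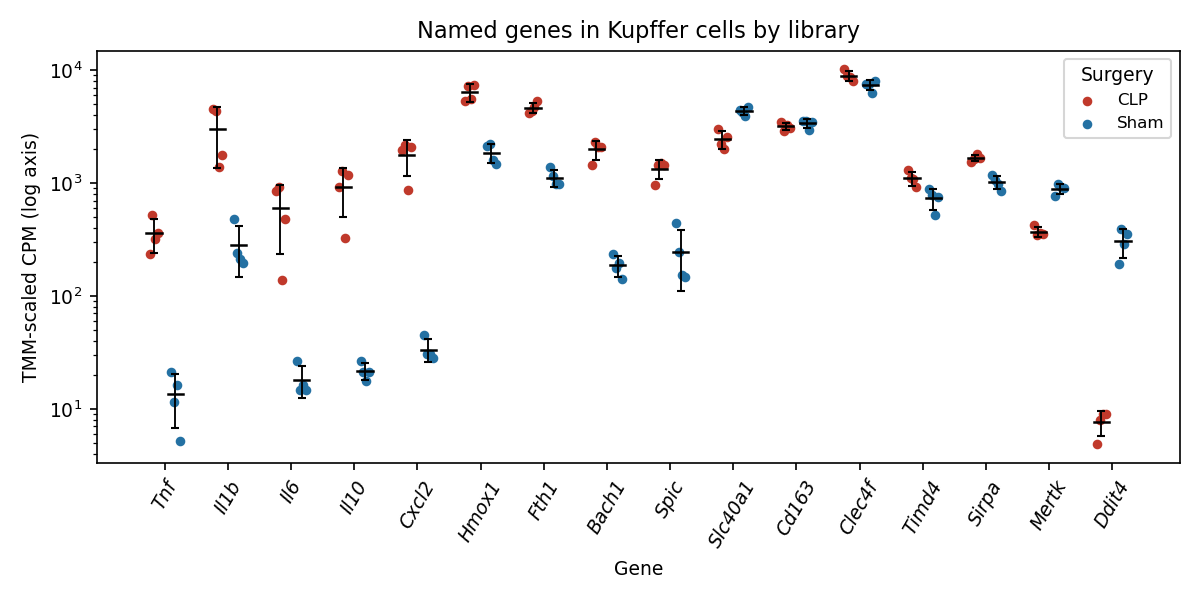
TMM-scaled CPM on a log axis for 16 named genes in the 4 CLP and 4 Sham libraries, as points with the mean and SD. Tnf, Il10, Cxcl2, Hmox1, Fth1, Bach1 and Spic lie higher in every CLP library than in any Sham library, Slc40a1, Mertk and Ddit4 lie lower, and Cd163 overlaps.

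Among receptors for the uptake of red cells and dead cells, 12 of 35 rose and 2, Mertk and Itgb5, fell (median log2 fold change 0.30; camera adjusted p = 0.0187, or adjusted p = 0.4 with an estimated correlation). The list shares 13 of its 37 entries with other lists, and its call was also lost without CLP replicate 1 (camera adjusted p = 0.061) and with total-count scaling (0.205). Itgav, an integrin subunit, rose by 1.56 ± 0.15 and the scavenger receptor Msr1 by 1.28 ± 0.13 on the log2 scale. Mertk, a receptor tyrosine kinase for dying cells, fell from 891 ± 92.4 to 371 ± 36.6 CPM (-1.27 ± 0.13). Sirpa, which receives the inhibitory signal of CD47 on red cells, was at 1663 ± 105 CPM in CLP and 1018 ± 137 CPM in Sham (0.71 ± 0.13, edgeR adjusted p = 9.5e-04), and Timd4, a phosphatidylserine receptor, at 1107 ± 155 CPM in CLP and 736 ± 156 CPM in Sham (0.59 ± 0.17, edgeR adjusted p = 0.0153). With total-count scaling neither was past the threshold (log2 fold changes 0.16 and 0.04). Vsig4, a complement receptor of tissue macrophages, was at 2352 ± 396 CPM in CLP and 1865 ± 267 CPM in Sham and did not pass (edgeR adjusted p = 0.0945). With the GC correction Vsig4 passed as higher (0.43, edgeR adjusted p = 0.0413), and with total-count scaling its log2 fold change was -0.21.

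Kupffer cell identity genes moved in both directions: 11 of 32 were higher and 6 lower, with a median log2 fold change of 0.22 and a list test that did not pass (camera adjusted p = 0.221). Of the 32 entries, 15 are also in other lists. The most abundant members were Clec4f, a Kupffer cell lectin, at 8920.2 ± 899.7 CPM in CLP and 7374 ± 740.0 CPM in Sham, and Cd5l, a secreted macrophage protein, at 6451 ± 683 CPM in CLP and 5316 ± 844 CPM in Sham. Their log2 fold changes were 0.27 ± 0.13 and 0.28 ± 0.15, with edgeR adjusted p-values of 0.0999 and 0.133. Both values turned negative with total-count scaling, at -0.28 and -0.27, and both passed as higher with the GC correction (edgeR adjusted p = 0.014 and 0.0336), Clec4f also with DESeq2 (adjusted p = 0.048). The sum of the list was 61575 ± 4474 CPM in CLP and 50443 ± 4573 CPM in Sham, a ratio of 1.22, higher in 4 of 4 CLP libraries (exact permutation test, two-sided, p = 0.0286, or 0.0743 adjusted over 13 sums). The list includes Hmox1, which rose from 1860 to 6375 CPM, and Spic, which rose from 246 to 1344 CPM. Slc40a1, also in it, fell from 4345 to 2450 CPM. The sum is therefore not by itself a measure of the share of Kupffer cells. With total-count scaling the ratio was 0.833.

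Coagulation and fibrinolysis genes rose in 19 of 24 cases and none fell (median log2 fold change 1.70; camera adjusted p = 1.3e-07, or adjusted p = 0.16 with an estimated correlation). Platelet and megakaryocyte markers rose as well (13 of 14), and the cell of origin was not measured. F3, tissue factor, which starts clotting, rose from 0.684 ± 0.163 to 36.5 ± 17.5 CPM. Plaur, the urokinase receptor, stood at 434 ± 95.4 CPM in CLP and 13.2 ± 5.25 CPM in Sham. Of 25 complement genes, 12 rose (13 adjusted over the list alone) and 2, C5ar2 and Cd46, fell (median 0.35; camera adjusted p = 0.00419, or adjusted p = 0.4 with an estimated correlation). With total-count scaling the complement list did not pass (camera adjusted p = 0.0948). The C1q receptor-like gene Cd93 rose by 2.23 ± 0.24, the C5a receptor C5ar1 by 2.19 ± 0.24 and the C3a receptor C3ar1 by 1.09 ± 0.13 on the log2 scale.

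Pattern recognition and inflammasome genes were split, with 23 of 42 higher and 8 lower (median 0.62; camera adjusted p = 8.5e-04, or adjusted p = 0.334 with an estimated correlation). The adaptor Ticam1 rose by 1.55 ± 0.12, the kinase Ripk2 by 1.97 ± 0.15 and the lectin receptor Clec4d by 4.13 ± 0.33 on the log2 scale. Antigen presentation genes rose in 12 of 22 cases, and 1, Psmb9, fell (median 0.58; camera adjusted p = 7.4e-04, or adjusted p = 0.423 with an estimated correlation). Cd274, the inhibitory ligand PD-L1, stood at 1678 ± 282 CPM in CLP and 114 ± 57.5 CPM in Sham. Of the costimulatory ligands, Cd86 was at 724 ± 119 CPM in CLP and 256 ± 33.0 CPM in Sham, and Cd80 rose by 2.30 ± 0.23 on the log2 scale.

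Interferon-stimulated genes did not move as a block: 18 of 43 rose, 5 (Ifit3, Ddx58, Cmpk2 and Igtp among them) fell, and the median log2 fold change was 0.21 (camera adjusted p = 0.0189, or adjusted p = 0.64 with an estimated correlation). Without CLP replicate 3 the list did not pass (camera adjusted p = 0.0593). Ifi205, of a family of near-identical genes, rose by 4.17 ± 0.22, the chemokine Cxcl10 by 2.83 ± 0.22 and the transcription factor Irf1 by 1.35 ± 0.12 on the log2 scale. Of 26 immediate early genes 15 rose and 4, Fos, Jun, Klf2 and Klf4, fell (5 adjusted over the list alone; median 1.13; camera adjusted p = 9.6e-04, or adjusted p = 0.423 with an estimated correlation). Fos, a subunit of the AP-1 factor, fell from 320.5 ± 41.4 to 60.3 ± 2.76 CPM (-2.41 ± 0.12), whereas the nuclear receptor Nr4a3 and the zinc finger factor Egr2 rose by 5.14 ± 0.33 and 3.68 ± 0.25 on the log2 scale.

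Glucocorticoid-responsive genes diverged, with 11 of 23 higher, 8 lower and no call for the list (camera adjusted p = 0.204). The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose from 64.2 ± 5.96 to 1052 ± 111 CPM and from 6.59 ± 1.99 to 337 ± 62.7 CPM, and Ddit4 of the same list fell as above. With total-count scaling that list passed (camera adjusted p = 0.0128), as it did with fry (adjusted p = 1.8e-04). Heat shock and chaperone genes also diverged: 4 of 16 (Hspa5, Hspa8, Dnajb4 and Bag3) rose and 6 fell, with a median log2 fold change of 0.09, a mean of -0.24 and no call (camera adjusted p = 0.575). The co-chaperones Bag3 and Dnajb4 rose by 1.48 ± 0.15 and 1.25 ± 0.16 on the log2 scale, and the inducible Hsp70 gene Hspa1a fell from 109 ± 69.6 to 12.4 ± 4.95 CPM (-3.13 ± 0.45). Hspa1a shares nearly all of its sequence with Hspa1b, so the division of reads between them is uncertain.

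**Figure D3:**
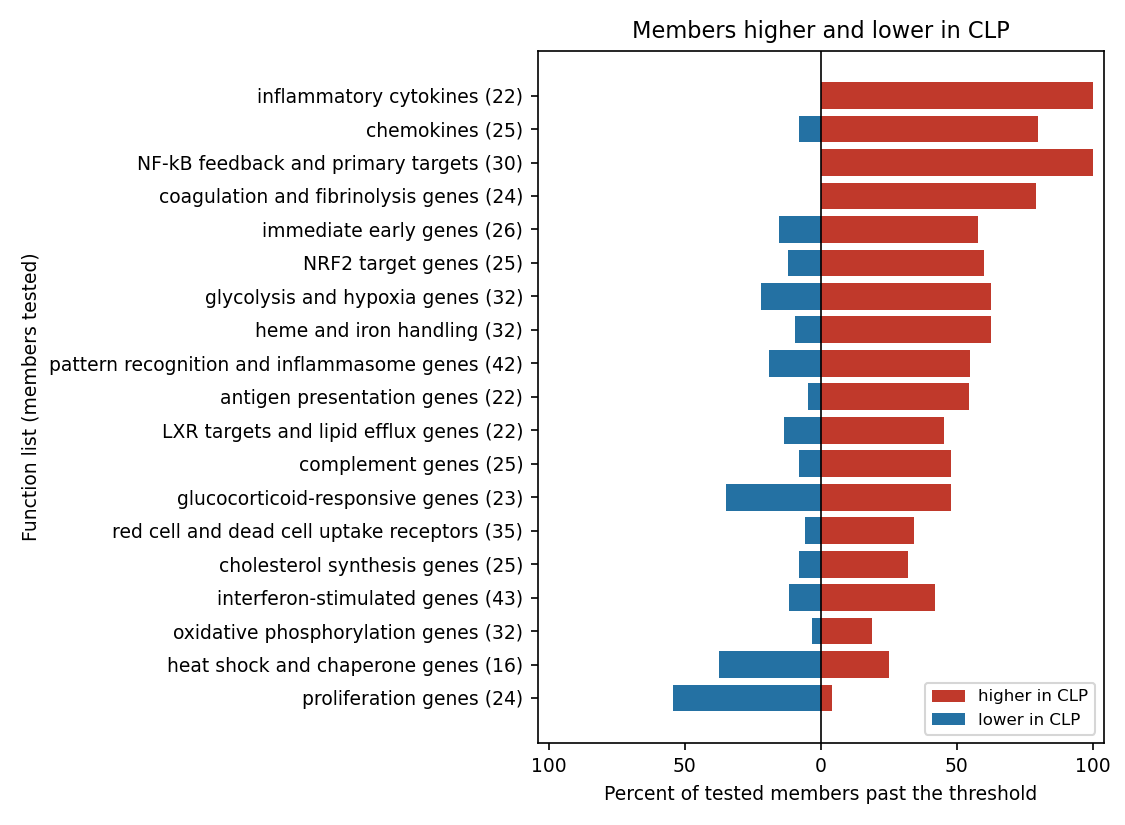
Percent of the tested members of each function list that were higher (red, to the right of 0) or lower (blue, to the left of 0) in CLP at an edgeR adjusted p of 0.05, with the number tested in brackets. All 22 cytokine and 30 NF-kB members were higher, and proliferation genes have the largest lower share, 13 of 24.

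In metabolism and redox control, 15 of 25 NRF2 target genes rose and 3, Keap1, Cat and Gsta3, fell (median 0.88; camera adjusted p = 6.2e-05, or adjusted p = 0.3 with an estimated correlation). The cystine transporter Slc7a11 had 4906 counts in CLP and 36 in Sham, a ratio of 204 with an exact 95% counting interval of 147 to 292, or 304 without Sham replicate 1. Besides Fth1, the autophagy receptor Sqstm1 rose by 2.58 ± 0.21 on the log2 scale. Glycolysis and hypoxia genes rose in 20 of 32 cases and fell in 7 (median 0.86; camera adjusted p = 3.3e-04, or adjusted p = 0.221 with an estimated correlation). Hexokinase 2 (Hk2) stood at 1104 ± 198 CPM in CLP and 216 ± 21.9 CPM in Sham, and Pgk1, a glycolytic kinase, and Adm, the vasodilator adrenomedullin, rose by 1.42 ± 0.11 and 4.01 ± 0.32 on the log2 scale.

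Cholesterol synthesis genes rose in 8 of 25 cases, and 2, Mvk and Lss, fell (median 0.22; camera adjusted p = 0.042, or adjusted p = 0.423 with an estimated correlation). The sterol regulators Insig1 and Srebf2, which control synthesis and are not synthetic enzymes, had log2 fold changes of 1.82 ± 0.14 and 1.07 ± 0.11. Of 22 LXR target and lipid efflux genes 10 rose (11 adjusted over the list alone) and 3, Nr1h3, Abcg1 and Mylip, fell (median 0.35; camera adjusted p = 0.0333, or adjusted p = 0.447 with an estimated correlation). The cholesterol ester hydrolase Nceh1 rose by 1.60 ± 0.17 and lipoprotein lipase (Lpl) by 1.11 ± 0.12, while the cholesterol exporter Abcg1 fell from 429 ± 50.6 to 132 ± 49.7 CPM, with 207 CPM in CLP replicate 1 and 102 to 112 CPM in the other CLP libraries. Without CLP replicate 1 neither list passed (camera adjusted p = 0.101 for cholesterol synthesis and 0.125 for LXR targets). The cholesterol list also missed the threshold without CLP replicate 3 (0.0519) or Sham replicate 3 (0.103), and the LXR list without Sham replicate 3 (0.0657). Neither passed with total-count scaling (0.205 and 0.199) or the stricter filter (0.0753 for both), and the cholesterol list also missed it with a block on replicate number (0.0535).

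Proliferation genes fell in 13 of 24 cases (median -0.98; camera adjusted p = 0.0189, or adjusted p = 0.64 with an estimated correlation). Without CLP replicate 3 the list did not pass (camera adjusted p = 0.0593), nor did it with total-count scaling (0.205), the stricter filter (0.144) or fry (0.115). The mitotic kinase Plk1 and the cyclin Ccne1 had log2 fold changes of -2.77 ± 0.47 and -1.76 ± 0.37. The proliferation marker Mki67 went the other way, at 470.0 ± 55.1 CPM in CLP and 122 ± 50.9 CPM in Sham (1.95 ± 0.27). Oxidative phosphorylation genes changed little, with 6 of 32 higher, 1, Ndufs3, lower and no call (camera adjusted p = 0.102). Adjusted over the list alone, 3 were higher, and without CLP replicate 2 or 4 the list passed (camera adjusted p = 0.0435 and 0.0356). Cycs, Uqcrfs1 and Atp5b had log2 fold changes of 0.53 ± 0.12, 0.42 ± 0.10 and 0.49 ± 0.12, and all 3 values turned negative with total-count scaling (-0.02, -0.13 and -0.06).

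Markers of other cells that a liver sort could hold differed between the groups. Markers near 0 in Sham were tested only if they were high in CLP, so counts of members higher lean upward. All 16 neutrophil markers tested were higher in CLP (median log2 fold change 3.88; camera adjusted p = 1.9e-07, or adjusted p = 0.3 with an estimated correlation), and the summed level of the 22 markers in the table was 556 ± 229 CPM in CLP and 133 ± 19.1 CPM in Sham (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows, and 0.0743 adjusted over 13 marker sums). The most abundant were Csf3r, the receptor for Csf3, at 246 ± 73.6 CPM in CLP and 99.1 ± 14.9 CPM in Sham, and Lcn2, a siderophore-binding protein that macrophages can also make, at 58.1 ± 39.1 CPM in CLP and 5.88 ± 4.54 CPM in Sham. Lcn2 was at 12.2 CPM in Sham replicate 2 and 1.86 to 6.02 CPM in the other Sham libraries, so its ratio depends on that library. Of 14 platelet and megakaryocyte markers 13 were higher (median 2.85; camera adjusted p = 2.6e-06, or adjusted p = 0.3 with an estimated correlation), with sums of 2017 ± 25.7 CPM in CLP and 966 ± 98.3 CPM in Sham, also higher in 4 of 4 CLP libraries. Most of that sum was Rap1b, a widely expressed small GTPase, at 1558 ± 40.1 CPM in CLP and 659 ± 71.5 CPM in Sham, and Clec1b, which Kupffer cells express, had a log2 fold change of -0.25 ± 0.15 (edgeR adjusted p = 0.189). Clec1b passed without CLP replicate 1 (log2 fold change -0.38, edgeR adjusted p = 0.026), as with sample weights in limma voom (adjusted p = 0.00668) and total-count scaling (edgeR adjusted p = 8.6e-04).

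Of 15 B cell markers 12 were higher and 1, Cd79b, lower (median 2.58; camera adjusted p = 3.7e-05, or adjusted p = 0.16 with an estimated correlation), yet the sum was 281 ± 44.1 CPM in CLP and 287 ± 17.5 CPM in Sham. It was set by Bank1 and Cd22, at 182 ± 41.6 CPM in CLP and 210.3 ± 12.7 CPM in Sham and 61.0 ± 6.44 CPM in CLP and 62.3 ± 3.49 CPM in Sham, and 11 members were under 1 CPM in Sham. Without CLP replicate 1 Bank1 was lower (log2 fold change -0.38, edgeR adjusted p = 0.00795), as with sample weights in limma voom (adjusted p = 0.00629) and total-count scaling (edgeR adjusted p = 0.00119), where Cd22 also passed as lower (5.8e-04). Of 7 T and NK cell markers tested, 5 (Lck, Cd2, Gzmb and Il7r among them) were higher and Klrk1 was lower (camera adjusted p = 0.0558), with Klrk1 at 19.5 ± 4.96 CPM in CLP and 41.0 ± 7.77 CPM in Sham and Cd4 at 21.3 ± 6.19 CPM in CLP and 16.3 ± 4.58 CPM in Sham. The sums were 52.7 ± 7.90 CPM in CLP and 60.2 ± 8.08 CPM in Sham. That list passed when 1 of CLP replicates 2, 3 and 4 or Sham replicates 1, 2 and 4 was left out (camera adjusted p = 0.0191 to 0.0361), with fry (0.00249), with the block (0.0307) and with total-count scaling (0.0045), where Cd4 turned negative (-0.16).

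Liver tissue markers had smaller median log2 fold changes than the neutrophil, platelet and B cell lists, which held more markers near 0 in Sham. The sums did not follow that order throughout. Their ratios were 1.41 for stellate, 1.27 for hepatocyte and 1.09 for endothelial markers. For neutrophil, platelet, B cell, and T and NK cell markers they were 4.17, 2.09, 0.98 and 0.88. With total-count scaling the hepatocyte, endothelial, stellate and monocyte sums were lower in CLP, with ratios of 0.869, 0.740, 0.963 and 0.934. That scaling also left the endothelial and stellate lists without a call (camera adjusted p = 0.0572 and 0.183). Of 26 hepatocyte markers 4 (Serpina3k, Fgb, Fgg and Hpx) were higher, 0 when adjusted over the list alone (camera adjusted p = 0.0667). Albumin (Alb) was at 2263 ± 354 CPM in CLP and 1710.3 ± 307 CPM in Sham and Serpina3k at 494 ± 29.3 CPM in CLP and 348 ± 69.1 CPM in Sham (edgeR adjusted p = 0.0569 and 0.0136), and the sums were 5592 ± 704 CPM in CLP and 4390.1 ± 662 CPM in Sham. Calls near the threshold moved with the method and with single libraries. Alb passed in 7 of the other settings that used all 8 libraries (adjusted p = 0.0206 with the GC correction in edgeR to 0.0483 with the stricter filter) and without CLP replicate 1 or Sham replicate 2 (edgeR adjusted p = 0.0437 and 0.0454), Serpina3k did not pass without Sham replicate 4 (0.0528), and the list passed without CLP replicate 1 or 4 or Sham replicate 2 (camera adjusted p = 0.0437, 0.0472 and 0.00923) and with a block on replicate number (0.0434). With total-count scaling Alb and Serpina3k turned negative, at -0.15 and -0.04. Of 24 sinusoidal endothelial markers 12 were higher and 1, Nrp1, lower (median 0.62; camera adjusted p = 0.00965, or adjusted p = 0.447 with an estimated correlation), with sums of 983 ± 36.4 CPM in CLP and 906 ± 64.3 CPM in Sham. Stab2 and Pecam1 had log2 fold changes of -0.05 ± 0.10 and -0.37 ± 0.15, and Pecam1 passed without CLP replicate 1 or Sham replicate 3 (edgeR adjusted p = 0.0306 and 0.00924) and as lower in 6 settings that used all 8 libraries, total-count scaling among them (edgeR adjusted p = 1.5e-04), where Stab2 also passed as lower (-0.60, edgeR adjusted p = 2.5e-04). Of 19 stellate cell and fibroblast markers 6 were higher and 2, Pdgfrb and Hand2, lower, or 1 adjusted over the list alone (median 0.43; camera adjusted p = 0.0333, or adjusted p = 0.447 with an estimated correlation). Their sums were 332 ± 25.9 CPM in CLP and 235 ± 16.0 CPM in Sham, with Ecm1 at 0.42 ± 0.11 and Hgf at 0.64 ± 0.28 on the log2 scale. That list did not pass without CLP replicate 3 or Sham replicate 3 or 4 (camera adjusted p = 0.0628, 0.0756 and 0.0545), and Hgf passed without CLP replicate 3 or 4 (edgeR adjusted p = 0.0234 and 0.0394). Ecm1 turned negative with total-count scaling (-0.13).

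Of 17 monocyte markers 7 were higher (median 0.41; camera adjusted p = 0.0333, or adjusted p = 0.334 with an estimated correlation), with sums of 2473 ± 198 CPM in CLP and 1809 ± 199 CPM in Sham. The integrin Itgal and the gene Plac8 had log2 fold changes of 0.42 ± 0.14 and 0.37 ± 0.19. The call of the list was lost without CLP replicate 3 or Sham replicate 3 or 4 (camera adjusted p = 0.0519, 0.0545 and 0.0535) and with the stricter filter (0.144), and that of Itgal without CLP replicate 1 or 3 or Sham replicate 3 or 4 (edgeR adjusted p = 0.0548 to 0.0905), with upper-quartile factors (0.0633) and with no low-count filter (0.0685). With total-count scaling Itgal and Plac8 turned negative, at -0.13 and -0.18. Dendritic cell markers gave no call (camera adjusted p = 0.725), with 1 of 8, Ccr7, higher and 1, Clec9a, lower, a median log2 fold change of -0.04 and a mean of 0.23. Their sums were 558 ± 77.9 CPM in CLP and 458 ± 50.9 CPM in Sham, and Cadm1 and Bst2 had log2 fold changes of 0.41 ± 0.17 and 0.21 ± 0.11. Cadm1 passed without CLP replicate 3 (edgeR adjusted p = 0.0382), with DESeq2 size factors (0.0453), the block (0.0241) and the GC correction (0.0221). Bst2 passed as higher with the GC correction (0.00382) and as lower with total-count scaling (0.0191), where Cadm1 was at -0.14. Of 9 erythroid markers 4 (Hbb-bs, Alas2 and Car2 among them) were higher, 5 adjusted over the list alone, and 2, Tmcc2 and Epor, lower. The erythroid list had a camera adjusted p of 0.221, or 0.049 without Sham replicate 2 and 0.0284 with fry, with sums of 38.9 ± 9.30 CPM in CLP and 29.4 ± 4.87 CPM in Sham. Alas2 at 0.91 ± 0.30 and Tmcc2 at -0.74 ± 0.25 on the log2 scale each missed the threshold when 1 of 4 libraries was left out. For Alas2 these were CLP replicates 2 and 4 and Sham replicates 1 and 3 (edgeR adjusted p = 0.0516 to 0.08), and for Tmcc2 CLP replicates 2 and 3 and Sham replicates 3 and 4 (0.0576 to 0.0729), as with the GC correction (0.0847). With total-count scaling Alas2 also missed it (log2 fold change 0.37, edgeR adjusted p = 0.29). Of 6 bile duct markers 1, Sox9, was higher (camera adjusted p = 0.224), with sums of 28.5 ± 14.1 CPM in CLP and 15.9 ± 2.96 CPM in Sham. Krt8 and Krt18 had log2 fold changes of 0.49 ± 0.22 and 0.93 ± 0.41 and passed without CLP replicate 1 (edgeR adjusted p = 0.0276 and 0.0155), Krt18 also without CLP replicate 2 (0.0394) and with DESeq2 (0.0343). Both passed with sample weights in limma voom (0.0346 and 0.0367) and with the GC correction (0.0189 and 0.0344), and Krt8 turned negative with total-count scaling (-0.07). The Y-linked genes Ddx3y and Uty were present in all 8 libraries, at 154 ± 19.5 CPM in CLP and 113 ± 6.50 CPM in Sham and 36.7 ± 3.90 CPM in CLP and 56.6 ± 2.90 CPM in Sham, and Ddx3y turned negative with total-count scaling (-0.10).

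**Figure D4:**
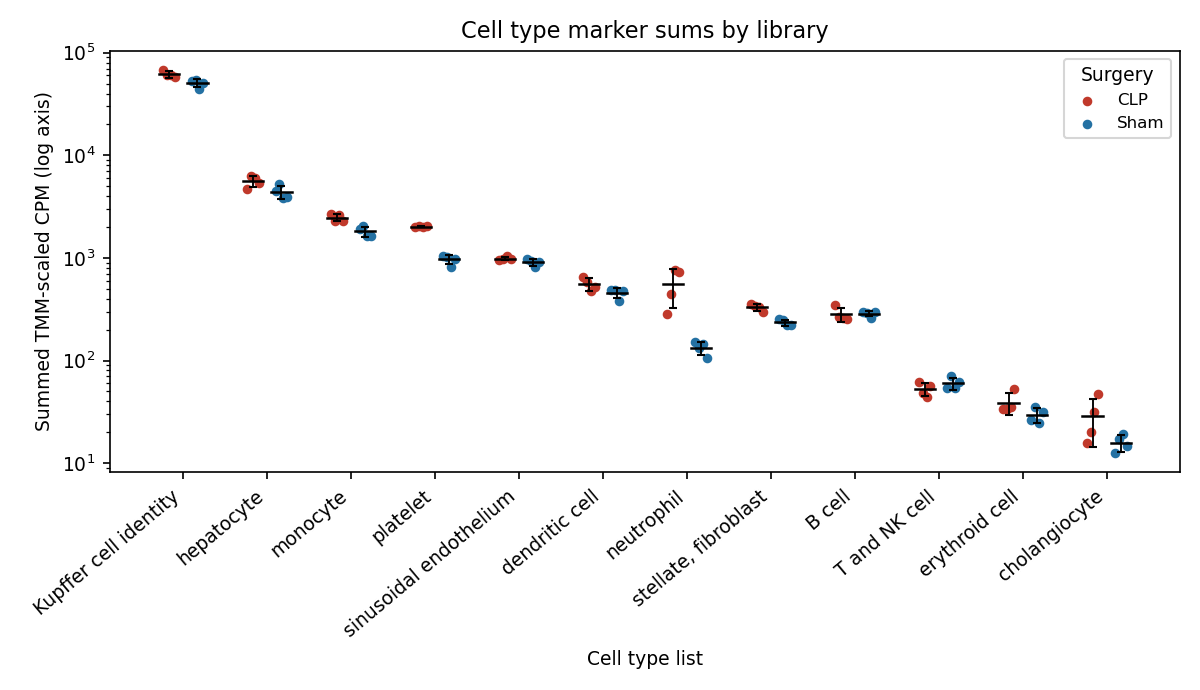
Summed TMM-scaled CPM on a log axis for 12 cell type marker lists in the 4 CLP and 4 Sham libraries, as points with the mean and SD. Neutrophil sums were 285 to 758 CPM in CLP and 107 to 149.8 CPM in Sham, below the Kupffer cell identity sums of 57408 to 67920.5 CPM in CLP.

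The list tests carry less weight than the counts of members. With a preset correlation of 0.01, 22 of the 31 lists tested passed camera, 21 upward and 1 downward, but 0 passed with an estimated correlation. The rotation test fry called 24. Splits of the same 8 libraries into 2 of each surgery on either side gave 3 to 15 lists, and splits of 3 and 1, which keep part of the surgery difference, gave 8 to 28.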

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

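The tests of mixing, of the marker correlations and of the splits were written before their results were seen. The slope for protein-coding genes and the test of a lower Kupffer cell share were written after the result was seen, and the patterns of CLP replicate 1 and of the cell type markers, like the symbol families, were picked after the data were seen. The comparison of genes and that of gene lists were set beforehand.

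A library is named here where its gap to the nearest of its group, over the range of the group, passed Dixon's 95% critical value. This held in 19 of 244 groups of 4 values, where chance gives about 1 in 20, or 12.2. CLP replicate 1 held 6 of them: Slamf1 at 46.7 CPM, Mertk at 425 CPM, Abcg1 at 207 CPM, Spic at 958 CPM, Cd22 at 70.7 CPM and the B cell marker sum at 347 CPM. Among other CLP libraries, the erythroid marker sum was 52.8 CPM in replicate 4 and the TMM factor 0.801 in replicate 2.

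Sham replicate 1 stood apart for Tnfrsf9 (0.0917 CPM), Cxcl2 (45.0 CPM), Il1b (485 CPM), Il6 (26.6 CPM) and Krt8 (4.98 CPM). Sham replicate 3 stood apart for Gna15 (18.9 CPM), Cd163 (2947 CPM), the dendritic cell marker sum (382 CPM), protein-coding counts (96.5%), Malat1 (1.69%) and Neat1 (0.0437%).

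The number of genes changed was reached by 1 of 35 splits of the 8 libraries, the real one, and no other split gave more than 2. For gene lists 6 of 35 splits gave as many as the real 22, and the highest of the others gave 28. The other splits that reached it held 3 libraries of one surgery and 1 of the other, and so kept part of the surgery difference, whereas the 18 splits with 2 of each gave 3 to 15 lists. The count over all splits leaves chance open for the lists. For symbol families 1 of 35 splits reached the real 19, and the highest other gave 18.

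CLP replicate 1 lay between the groups on the first principal component, at -45.2. The other CLP libraries were at -82.3 to -78.2 and the Sham libraries at 59.4 to 82.9. On the second component it lay beyond both groups, at 58.6. Were Sham RNA mixed into CLP replicate 1 and nothing else changed, raised and lowered genes should need the same share. They needed 0.440 (95% interval 0.359 to 0.493) and 0.0768 (0.0264 to 0.110). These intervals resample genes within a library and leave out the spread between libraries. In CLP replicates 2, 3 and 4 the intervals did not overlap either. In replicate 2 they were -0.260 to -0.159 for raised and -0.0314 to -0.00807 for lowered genes. The test therefore cannot decide about mixing, and Sham RNA, alone or beside another cause, is not excluded. CLP replicate 1 had the lowest Malat1 and Neat1 shares of the 8 libraries, 0.510% and 0.0164%, and the highest protein-coding share, 98.3%. Loss of noncoding RNA alone would spare protein-coding genes. Yet their response in CLP replicate 1 had a slope of 0.752 against the mean of the other CLP libraries, and the remaining genes had 0.736. For protein-coding genes the other CLP libraries had 1.02 to 1.08. Their reference mean included CLP replicate 1, which can raise these slopes, so the gap may be overstated. A weaker or earlier response behind CLP replicate 1 could give these shares and slopes and was not tested.

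Most neutrophil, B cell and platelet markers tested were higher in CLP. The B cell rise lay mainly in 11 markers under 1 CPM in Sham, and the ratio of the B cell sums was 0.98. A lower share of Kupffer cells, if it let in all other cells alike, should raise hepatocyte, endothelial and stellate markers as much. The medians differed by 2.59 (95% interval 2.18 to 2.95). That cannot argue against a lower share, because the raised lists were picked for their rise. Neutrophils, B cells or platelets alone could also lower the share. If the cells were carried along, their markers of low baseline should vary together over the CLP libraries: the median pairwise correlation was 0.875 for neutrophil, 0.327 for B cell and 0.929 for platelet markers, against 95th percentiles of 0.830, 0.750 and 0.799 in matched raised genes. Carried neutrophils and platelets could account for part of those signals, and the B cell test cannot tell. These correlations rest on 4 libraries and on 9 neutrophil, 11 B cell and 6 platelet markers. Genes raised together within Kupffer cells could also correlate, so the test does not separate the 2 origins. Expression by the Kupffer cells themselves was not tested.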

How the results depend on the processing

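Over the alternatives set in advance 6960 to 9420 genes passed, except 6076 with the stricter filter, where fewer genes were tested and 2472 changed at least 2-fold. No gene called in the main fit had a log2 fold change of the opposite sign under them. Total-count scaling gave 1715 genes higher and 8292 lower. Under it, 770 genes called in the main fit had the opposite sign, whether or not they passed there, and 3 did with the GC correction. No list passed with an estimated correlation (0 of 31). In the 22 lists called at the preset of 0.01 the estimate was higher, from 0.0416 for B cell markers to 0.855 for proliferation genes. A block on replicate number gave 7794 genes. The libraries share only a number: correlations between those of the same number were 0.17, -0.12, 0.13 and -0.09, and 0 libraries correlated best with their own number.

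Of 1798 values of named genes, 1708 kept their direction and side, 45 became stronger, 20 weaker and 25 reversed. For list tests these were 360, 19, 49 and 2 of 430. Reversed log2 fold changes, none large, were those of Cd22 (0.0150 with DESeq2, 0.0314 with DESeq2 size factors, 0.00174, 0.00813 and 0.0135 without CLP replicates 2 and 4 and Sham replicate 1, where leaving out single libraries gave -0.106 to 0.0135, 0.12 with the GC correction), Stab2 (0.0125 with DESeq2 size factors, 0.0684 with the GC correction) and Cd163 (0.0198 with the GC correction). With total-count scaling they were Cycs -0.0231, Uqcrfs1 -0.13, Atp5b -0.0607, Clec4f -0.28, Vsig4 -0.21, Cd5l -0.27, Alb -0.15, Serpina3k -0.0401, Ecm1 -0.13, Itgal -0.13, Plac8 -0.18, Cd4 -0.16, Cadm1 -0.14, Bst2 -0.34, Krt8 -0.0662 and Ddx3y -0.0991. That scaling lowers all values by construction. The dendritic cell list (adjusted p = 0.897, camera, stricter filter) and the oxidative phosphorylation list (adjusted p = 0.312, camera, total-count scaling) also reversed, and the cause was not tested.

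The ratio of the B cell marker sums was 1.02 with DESeq2 size factors. With total-count scaling ratios were 0.833 for Kupffer cell, 0.869 for hepatocyte, 0.740 for endothelial, 0.963 for stellate, 0.934 for monocyte, 0.831 for dendritic, 0.902 for erythroid and 0.754 for sex-linked genes, and moved further down to 0.668 for B cell and 0.597 for T and NK cell markers. No spike-in or cell count was at hand to choose between scalings.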

Other observations

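Genes were grouped by the letters that open their symbols, and 80 groups of at least 15 genes were tested with camera. The grouping was chosen after the data were seen, and no group passed with an estimated correlation. Zinc finger genes named Zfp fell most clearly: 218 of 331 were lower and 40 higher, with a median log2 fold change of -0.89 (camera adjusted p = 2.0e-10, or adjusted p = 0.49 with an estimated correlation). Histone genes (Hist) were lower in 25 of 49 cases and higher in none, and Kelch-like genes (Klhl) in 19 of 26 (adjusted p = 0.73 and 0.353 with an estimated correlation, camera). Interleukin and receptor genes (Il) were higher in 28 of 44 cases, with adjusted p = 0.353 with an estimated correlation (camera). Ribosomal protein genes of the large subunit (Rpl) were higher in 29 of 58 cases with a median of 0.31, which turned to -0.24 with total-count scaling.

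The fall of Zfp transcripts kept its sign in all 19 settings, with medians from -1.44 to -0.69. Other genes of like mean expression fell less: 10000 random lists matched on it had a median of -0.17 and a lowest value of -0.39. With matching on GC content and transcript length the median was -0.0105 and the lowest -0.21. Matching on all 3 gave -0.13 and -0.33. These properties did not bring a fall of this size in other genes. The family was picked from 80 for its fall, and genes were drawn independently. The draws therefore do not measure chance for genes that vary together. Short half-lives of these transcripts, or reads shared between related genes, could produce such a fall, and neither was tested.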
